A study of Zea mays with 2182 samples.

How the data were processed

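Maize anthers of the inbred line W23, dissected at 11 lengths from 0.5 to 3.0 mm, were fixed, digested and sorted into single cells on a Hana cell sorter with the FX-Cell procedure, and libraries were made with CEL-Seq2, per the labels' protocols. The design text states that at least 2 plants gave anthers for each stage; no label ties a cell to a plant. HISAT2 and the maize build B73 RefGen_v4 are named in the submitters' processing notes; the aligner's version, the counting tool and any filter on cells or genes are not given in the sources used here. The authors deposited 1 table of UMI counts (whole numbers, not normalised) with 22173 rows and 2182 cells, each cell being a separate sample, and 0 groups of cells had identical counts. Every row had a count in at least 4 cells, and totals ran from 251 to 50159 UMIs per cell. UMIs count captured molecules, so amplification is removed, but only a small part of each cell's transcripts is captured and intervals cover counting error only.

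Rows were named as in the table: 21635 gene IDs of the v4 annotation, 139 older gene IDs, 163 gene symbols, 226 PHAS loci (0.166% of UMIs) and 10 microRNA precursors. The reference table given for naming belongs to the assembly Zm-B73-REFERENCE-NAM-5.0, another build, so no coordinates were used; it matched 158 of the symbols and 0 of the v4 IDs, and most genes are therefore counted without a name. The 27 gene lists fixed before the data were examined included 19 that match on gene descriptions, which the reference table does not hold, so these checks are void; of the 8 lists matched on symbols, RAD51B (germinal and meiosis), CR4 (epidermis), SGS3 (phasiRNA) and C2 (flavonoid) were the only members with a row, and the tapetum, vascular, niche patterning and jasmonate lists had 0. Further lists (21PHAS, 24PHAS, miR159 precursors, plastid-encoded genes, nuclear photosynthesis, chromatin and DNA replication, alpha-tubulin, aquaporin, cytosolic ribosomal protein and pollen genes) were drawn up from the table's own symbols after levels per length had been seen.

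Lengths, sets, set numbers and wells came from the cell titles. What the set number stands for is not given in the sources used here; a set, number and length together are called a pool (60 pools, 45 of them with at least 8 analysed cells). Cells with at least 500 UMIs (1658) were kept. The median was 1970 UMIs and 1477 detected genes per cell at 0.5 mm, 2162 and 1380 at 2.0 mm and 1008 and 554 at 3.0 mm. Cells were dispensed singly and no doublet caller was run, so doublets were not removed.

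Raw counts were summed over cells, since cells are not replicates. For trends, the 11 sums were fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with the design, quasi-likelihood F-test of the slope on length in mm, Benjamini-Hochberg false discovery rate of 0.05); the squared term was tested the same way on centred length. CPM values are UMIs scaled to a common total of summed UMIs, without TMM factors. Slopes are log2 units per mm, with a standard error taken from the slope and its F statistic. Gene lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count of 2) with correlation 0.01 and with an estimated correlation. The genes to be named followed a rule fixed before the data were examined: past the test, a mean of at least 100 CPM, the same sign with set as a covariate and within sets 1.4.21 and 8.18.21, and with a symbol, the 12 largest slopes each way; 12 rising and 9 falling genes met it. Per cluster the 5 largest slopes each way were named, and members of the lists with the largest slopes.

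Cells were clustered with scanpy 1.11.5 (counts per 10000 and log, 2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution 1) into 17 clusters numbered by size, and again without PHAS and microRNA rows into 18. Within clusters, sums of at least 5 cells per length were fitted as above for clusters with at least 6 lengths. Whether clusters recur in wells was tested by permuting cluster names within pools 1000 times. Clusters 6 and 8, with over 2 times the permuted mean of same-well pairs and a permutation p under 0.05 when multiplied by the number of clusters, are called clusters with recurring wells (216 cells, 13.0%), as are clusters 6 and 7 of the clustering without PHAS and microRNA rows (232 cells, 13.99%). Alternatives for trends leave out the former, and PHAS and microRNA values outside recurring wells leave out the latter, so that PHAS rows did not choose the cells. Likeness of clusters to the other cells of their pool was the median over pools of the correlation of log CPM at 5000 UMIs per sum. Pools were compared with each length by correlation over 4086 genes of log2(CPM + 20), centred over lengths and without PHAS and microRNA rows. In that comparison 31 of the 45 pools matched best a length within 0.25 mm of their own, taken from the other sets, and 42 within 0.5 mm.

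Alternatives were RLE size factors and the Wald test of DESeq2 1.42.0, no filter on low counts, no minimum or at least 2000 UMIs per cell, equal weight per cell with limma, set as a covariate or as a subset, a replicate block by set and number, log2 of length, other clusterings, and leaving out each length; library size scaling and leaving out pools, set MiSeq or clusters 6 and 8 were added after the data were seen. The steps were tested on simulated data with known answers: over the 11 lengths 14.9%, 80.6% and 100% of slopes of 0.5, 1 and 2 log2 units per mm were recovered among 5584 genes, and squared terms of 1 and 2 were recovered at 47% and 84% among 6889 genes. Simulated pools were placed at their own length in 11 of 11 cases, but they were drawn from the same sums they were compared with. That result therefore does not measure how well pools are placed against other sets. For the likeness of clusters 6 and 8 to their pools, the bound written beforehand was met, but by less than the spread, a margin added after the value had been seen, and the outcome was set to undecided. The photosynthesis genes also met their bound, of 50% of the slope, by less than the error, and that test was then set to undecided because the genes lead the cluster left out. The test of zma-MIR2275c against 24PHAS was narrowed to cells outside recurring wells, and its reassignments from lengths to pools, after earlier results had been seen; within lengths the permutation p was 1e-05. Profiles without set Pilot and the split of pollen genes were also added after earlier results. Tests whose outcome followed from how the pools, cells or clusters had been picked (other pools of the same length, the spread of 21PHAS UMIs over cells, and clusters with both PHAS classes) were left out. For several alternatives the share of tested genes is printed in place of the count, a choice of presentation made after the counts were computed; whether a count moved by over 1.5 times was judged on the counts. Figures were drawn with matplotlib 3.10.9.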

Results

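Single-cell transcriptomes were collected from maize anthers of the fertile inbred line W23. The anther is the male floral organ, in which somatic wall layers surround the cells that enter meiosis and become pollen. Anthers of 11 lengths from 0.5 to 3.0 mm were fixed, digested and sorted into single cells on a Hana cell sorter, and their 3' transcript ends were counted with CEL-Seq2, a method that tags each captured molecule with a unique molecular identifier (UMI). The table held 2182 cells and 4117098 UMIs, with a median of 1009 UMIs per cell. The 1658 cells with at least 500 UMIs were analysed, with the fewest, 89, at 3.0 mm and the most at 2.0 mm. Summed UMIs per length ran from 132940 at 3.0 mm to 1496508 at 2.0 mm. The cell titles opened with 1 of 6 words or dates, called sets here, and the sets did not cover the lengths evenly: set 8.18.21 gave 784 of the cells, while set Pilot and the 28 cells of set MiSeq were all from 2.0 mm anthers. Titles assigned no cell to a plant, so the cells of each length were summed to 1 sample and the comparisons were trends over the 11 lengths. The p-values therefore measured the scatter of lengths around a fitted course.

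The first comparison asked which genes rose or fell as anthers lengthened. Several nuclear genes of photosynthesis were among those that rose. RBCS, the small subunit of Rubisco, went from 61.4 ± 28.1 CPM (UMIs scaled to a common library total, mean ± SD of the 3 shortest lengths) to 1217 ± 431 CPM (3 longest lengths), a slope of 2.37 log2 units per mm (SE 0.19). CAB1, a chlorophyll a/b binding protein, rose from 294.7 ± 38.6 to 2297 ± 516 CPM, and the photosystem subunit genes PSAH and PSBQ1 had slopes of 2.32 (SE 0.26) and 1.69 (SE 0.22). C2, the chalcone synthase that opens the flavonoid pathway, rose from 226.3 ± 71.6 to 3543 ± 480 CPM (slope 2.20, SE 0.17), and the aquaporin gene SIP1-2 rose from 131.3 ± 37.9 to 610.1 ± 175.3 CPM. C2 was uneven between cells, at 9425 CPM in cluster 5 and 110.03 CPM in cluster 2. Cluster 5 had 2 cells at 0.75 mm and 25 at 2.75 mm, lengths with similar numbers of analysed cells. The summed values of C2 do not tell a larger share of such cells from a higher level within them. At 0.5 mm all 12 UMIs of RBCS, most of those of CAB1 and 85 of 90 of C2 were from pool 7 of set 8.18.21. Without this pool, an alternative chosen after the data were seen, C2 had a slope of 2.68, RBCS of 2.56 and CAB1 of 1.80. UMIs of plastid-encoded photosystem genes also rose, psbB with a slope of 1.57 (SE 0.23), psbH 1.33 (SE 0.18), psbA 1.16 (SE 0.20) and psbC 1.15 (SE 0.15). So did UMIs of the plastid NADH dehydrogenase genes ndhG (0.91, SE 0.22) and ndhI (0.84, SE 0.24). How well CEL-Seq2 captures plastid RNA was not tested, so values of plastid genes here and below are of captured UMIs.

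Several genes of chromatin and DNA replication fell over the same lengths. HMGIY2, an HMG-I/Y chromatin protein, fell from 2473 ± 879 to 274.2 ± 22.1 CPM (slope -1.31, SE 0.20). DMT105, a chromomethylase of DNA, fell from 342.3 ± 17.6 to 32.1 ± 19.9 CPM (slope -1.54, SE 0.22), and ROA2, named in maize as a replication origin activator, from 278.1 ± 19.2 to 28.8 ± 19.6 CPM (slope -1.55, SE 0.23). The mitochondrial chaperonin 60 genes CPN60II and CPN60I had slopes of -0.96 (SE 0.20) and -0.63 (SE 0.18), RPS4 -0.76 (SE 0.12) and the ribosomal protein gene RPL17 -0.63 (SE 0.15). SGS3, a protein needed with RNA-dependent RNA polymerase for trans-acting small interfering RNAs, fell from 1050 ± 231.6 to 330.3 ± 67.0 CPM (slope -0.56, SE 0.15). MNB1B, an HMG box protein, had a slope of -0.42 (SE 0.15) with an adjusted p of 0.0433 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and it lost the call when any of 7 single lengths was left out. Of the 4 genes on the lists fixed beforehand that had a row in the table, C2 rose and SGS3 fell, both also when adjusted over the list alone, and RAD51B and CR4 had too few UMIs to be tested.

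**Figure D1:**
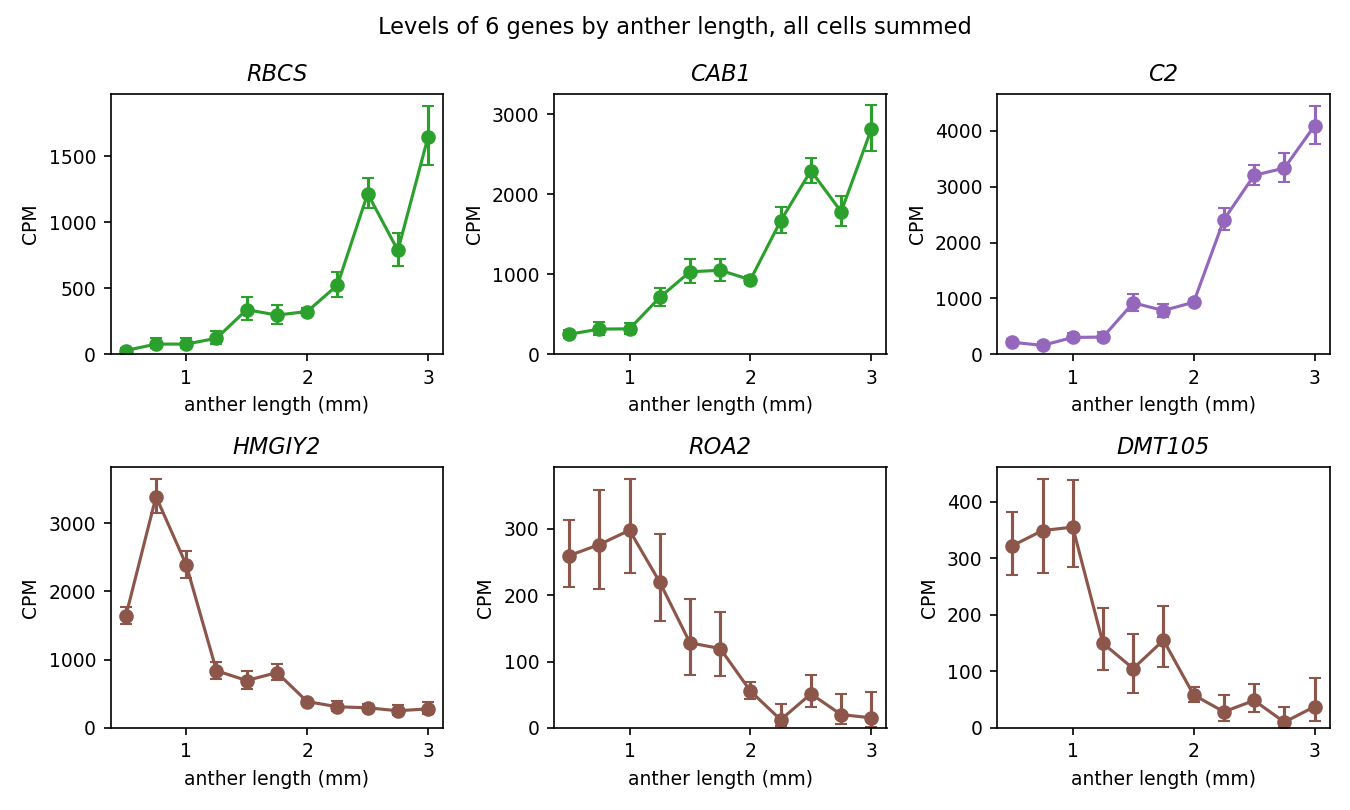
Scaled UMI counts (CPM, y axes, linear from 0) of RBCS, CAB1, C2, HMGIY2, ROA2 and DMT105 against anther length in mm (x axes), all cells of a length summed; points are the 11 lengths and bars are 95% Poisson intervals, which cover counting error only. RBCS went from 28.9 CPM at 0.5 mm (0 without pool 7 of set 8.18.21) to 1647 CPM at 3.0 mm and C2 from 216.5 CPM (14.2 without that pool) to 4092 CPM, while HMGIY2 went from 1638 to 278.3 CPM and ROA2 from 259.8 to 15.0 CPM.

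In all, 1670 of 5537 tested genes passed edgeR's quasi-likelihood test at a false discovery rate of 0.05, of which 885 rose and 785 fell. Of 91 genes with a symbol tested, 26 rose and 16 fell. These directions are relative to the median gene: without TMM factors, scaled by library size alone, the median slope was -0.23 log2 units per mm and 2018 genes passed, 490 up and 1528 down, and 1275 of the 1670 genes kept their call. With set and number as a replicate block only 4.05% of 4397 tested genes passed, and 83.7% of these rose. Within set 1.4.21 alone 28.2% of 1042 tested genes passed and within set 8.18.21 alone 719 of 4073, and 88.4% and 95.7% of these calls were among the 1670. The cells of these sets are also part of the sums that gave the 1670 genes, so this overlap is not independent replication. RBCS had slopes of 3.62 and 2.05 within these sets, C2 1.78 and 2.28, and HMGIY2 -2.19 and -1.17. The rule for naming required the same sign within both sets, so the shared sign of these genes was fixed by their selection.

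Groups of related genes were then tested as lists drawn up from the symbols in the table after levels per length had been seen, so their directions are not independent evidence. All 7 tested genes of the chromatin and DNA replication list fell, among them the flap endonuclease gene FEN1 (slope -1.17, SE 0.17) and MAD2 of the spindle checkpoint (-1.04, SE 0.33). All 5 tested genes of the nuclear photosynthesis list rose, among them the ferredoxin gene FDX3 (0.48, SE 0.14). FDX3 did not share the cell pattern of the others: it stood at 62.2 CPM in cluster 2 and 220.3 CPM in cluster 5. CAB1 (6290 and 214.8 CPM), RBCS (2767 and 67.2 CPM), PSAH and PSBQ1 were higher in cluster 2. The list values therefore include a gene unlike the rest. Of 6 tested aquaporin genes 5 rose, including NIP1-1 (0.96, SE 0.17) and PIP1-3 (0.81, SE 0.18), while TIP1-1 was at 0.04 (SE 0.27). Of the 23 genes on the plastid-encoded list 9 rose, among them cemA (0.84, SE 0.15) and atpI (0.68, SE 0.15), and 14 did not pass. The list left out ycf70, which also rose (0.55, SE 0.14), and rps3, which did not pass (0.02, SE 0.16). The 4 alpha-tubulin genes did not pass, and of 4 tested genes on the cytosolic ribosomal protein list 2 fell and 2 did not pass. RPS4, which fell (-0.76, SE 0.12), was not on that list. Camera with a preset correlation of 0.01 called 4 of 7 lists, with adjusted p of 0.000216 for chromatin and replication, 9.25e-06 for nuclear photosynthesis, 0.000217 for the plastid genes and 0.002 for the aquaporins. With an estimated correlation only chromatin and replication held (adjusted p = 0.018); the adjusted p with an estimated correlation was 0.059 for nuclear photosynthesis, 0.0774 for aquaporins and 0.512 for the plastid genes. Camera with the preset correlation gave the remaining lists adjusted p of 0.263 (24PHAS loci), 0.478 (cytosolic ribosomal proteins) and 0.566 (alpha-tubulins).

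Transcripts of the loci that yield phased small RNAs were highest at different lengths for the 2 classes. Maize anthers make both size classes of these RNAs, and the table counted transcripts of loci named 21PHAS and loci named 24PHAS. UMIs of 21PHAS loci stood at 1109 CPM (1010 to 1215, 95% Poisson interval, counting error only) at 0.5 mm, 1926 CPM (1741 to 2125) at 0.75 mm and 1389 CPM (1245 to 1544) at 1.0 mm, against 18.7 CPM (5.10 to 47.9) at 1.25 mm, 291.4 CPM (216.3 to 384.2) at 1.5 mm and 0 UMIs at 2.75 mm, which allows up to 15.0 CPM. UMIs of 24PHAS loci stood at 48.5 CPM at 0.75 mm and 28.6 CPM at 1.0 mm, rose to 1908 CPM (1728 to 2103) at 1.25 mm, 7599 CPM (7192 to 8023) at 1.5 mm and 7463 CPM (7111 to 7828) at 1.75 mm, and were at 0 UMIs at 2.25 mm, which allows up to 12.2 CPM. The zma-MIR2275c transcript, precursor of a microRNA of the family that directs cleavage of 24PHAS transcripts, was at 247.9 CPM (185.7 to 324.2) at 1.25 mm, 110.7 CPM (66.7 to 172.9) at 1.5 mm and 31.0 CPM (12.5 to 63.9) at 1.75 mm. No test was made of these differences between single lengths.

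The sets shared parts of these windows. At 1.5 mm 24PHAS loci were at 3914 CPM in set 1.4.21, 6958 CPM in set 3.29.22 and 9969 CPM in set 8.18.21, but at 1.75 mm they were at 10842 CPM in set 8.18.21 and 14.2 CPM in set 1.4.21. At 0.75 mm 21PHAS loci were at 3369 CPM in set 1.4.21 and 1334 CPM in set 7.21, while at 0.5 mm they were at 1255 CPM in set 8.18.21 and 40.1 CPM in set 1.4.21, and at 1.0 mm at 1623 and 27.8 CPM. When cells were clustered without PHAS and microRNA rows, clusters 6 and 7 of that clustering (13.99% of cells) had members that recurred in the same well numbers of different pools, as had clusters 6 and 8 of the clustering with all genes. These cells carried 92.2% of the 24PHAS UMIs and 98.1% of the zma-MIR2275c UMIs at 1.25 mm. Outside them 24PHAS stood at 272.9 CPM at 1.25 mm, 6310 CPM at 1.5 mm and 7113 CPM at 1.75 mm. The 1109 CPM of 24PHAS at 0.5 mm came from pool 7 of set 8.18.21, with 17.1 CPM in the other cells of that length, and the 759 CPM at 2.0 mm came from set MiSeq, with 16.9 CPM in the other sets.

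**Figure D2:**
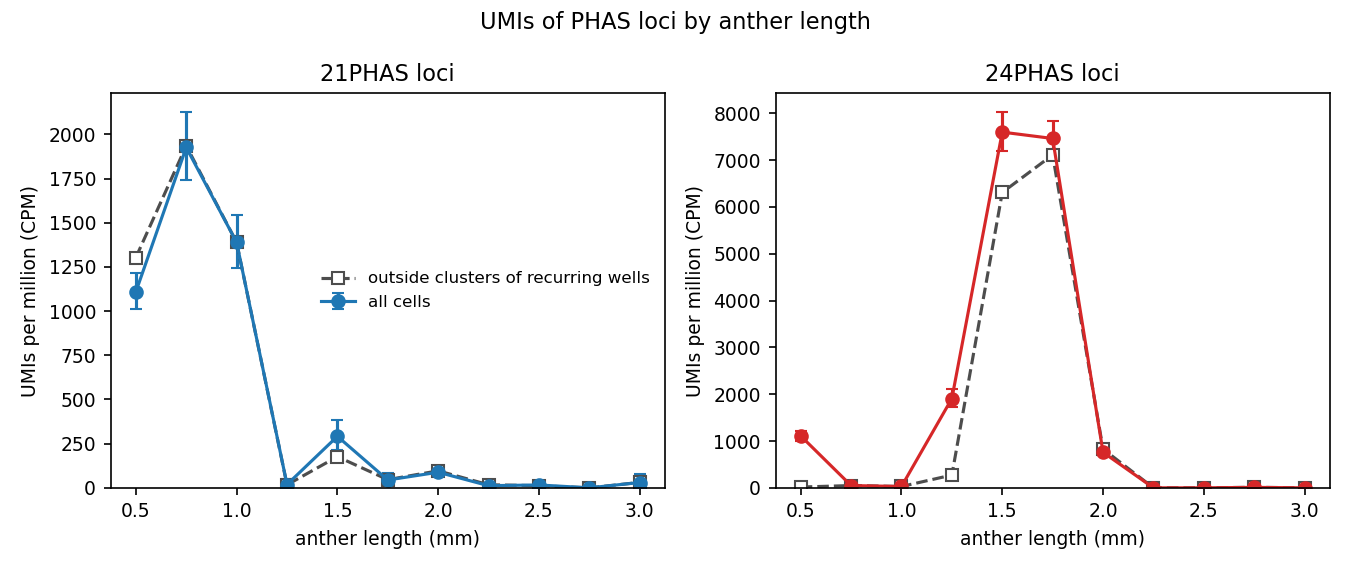
Scaled UMI counts (CPM, y axes, linear from 0) of all 21PHAS loci (left) and all 24PHAS loci (right) against anther length in mm (x axes); filled points are all cells of a length with 95% Poisson intervals for counting error, open squares are the cells outside the clusters of recurring wells in the clustering without PHAS and microRNA rows. In all cells the 21PHAS loci were highest at 0.75 mm with 1926 CPM and the 24PHAS loci at 1.5 mm with 7599 CPM.

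**Figure D3:**
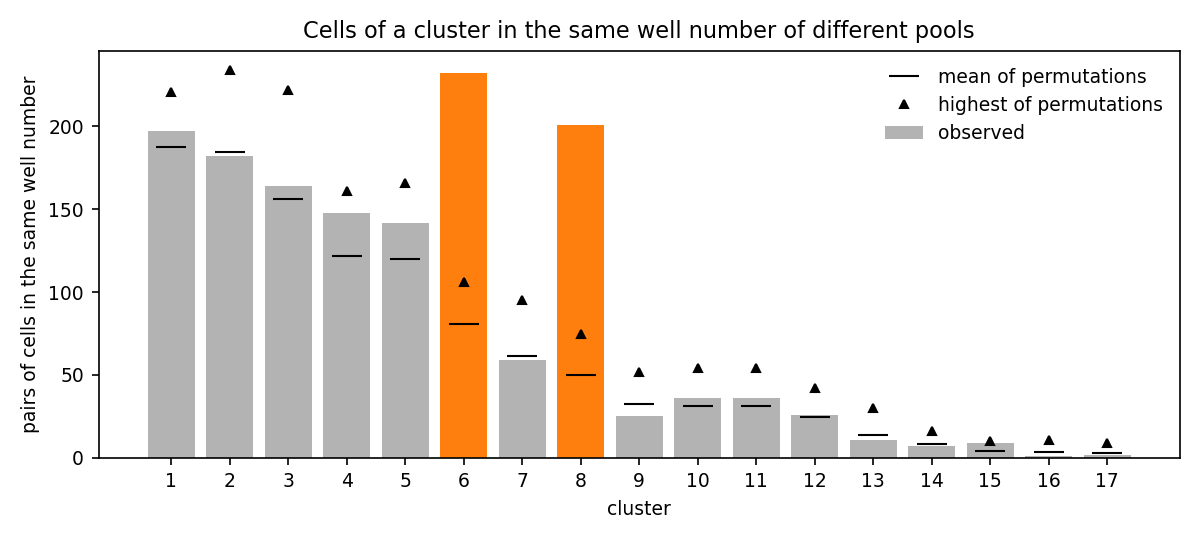
Pairs of cells of a cluster that had the same well number in different pools (y axis, number of pairs) for the 17 clusters from all genes (x axis); bars are observed pairs (orange for clusters 6 and 8), dashes the mean and triangles the highest of 1000 permutations of clusters within pools. Clusters 6 and 8 had 2.87 and 4.01 times the mean of the permutations, against 1.31 and 1.50 times in their highest permutation.

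The 21PHAS transcripts sat in few cells, and the 24PHAS transcripts, at the lengths where they stood highest, in a larger share of cells. With every cell thinned to 500 UMIs, 10.5% of the cells at 0.75 mm had a 21PHAS UMI (exact 95% interval 5.88 to 17.0, 17.3% before thinning), and the 7 cells with the most held 95.2% of these UMIs. At 1.5 mm 41.4% of the thinned cells had a 24PHAS UMI (32.9 to 50.2, 45.9% before thinning), and the 7 cells with the most held 39.0%. At 1.75 mm 44.0% of the thinned cells had a 24PHAS UMI (35.6 to 52.6, 51.8% before thinning), and the 7 cells with the most held 52.3%. Outside the clusters of recurring wells the thinned shares for 24PHAS were lower, 29.5% (21.0 to 39.2) at 1.5 mm and 38.0% (29.3 to 47.3) at 1.75 mm. There the 7 cells with the most held 53.9% and 64.9%. For 21PHAS at 0.75 mm the share there was 10.6%. Such shares depend on the level, 1926 CPM for 21PHAS at 0.75 mm and 7599 CPM for 24PHAS at 1.5 mm. At 1.25 mm, with 24PHAS at 1908 CPM, its thinned share was 26.7% (19.7 to 34.7). Outside the recurring wells it was 8.42% at 272.9 CPM. In the clustering without PHAS and microRNA rows, cluster 4 held 70.0% of all 21PHAS UMIs at 4427 CPM and 0.658% of the 24PHAS UMIs, and cluster 14 (39 cells, 18 of them from 1.75 mm) held 59.7% of the 24PHAS UMIs at 36312 CPM, with a 24PHAS UMI in each of its 39 cells. Another 35.9% of the 24PHAS UMIs lay in cluster 6, 1 of those with recurring wells. No marker of a cell layer from the lists fixed beforehand was detected widely enough to name these clusters.

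The second comparison asked which genes were highest or lowest at middle lengths, from the squared term of a quadratic fit. Of 7332 tested genes 62 passed edgeR's quasi-likelihood test, 57 with a negative term (high in the middle) and 5 with a positive term, and 12 of the 62 also passed the straight trend. No named gene met the rule for naming. The gene IDs Zm00001d012176 and Zm00001d047438 had no UMIs at the 3 shortest lengths and peaked at 428 CPM at 2.0 mm and 369.4 CPM at 2.25 mm, with terms of -5.99 (SE 0.76) and -5.97 (SE 0.77) log2 units per square mm and an adjusted p of 0.00183 each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Outside the rule, chosen after their values were seen, zma-MIR2275c had a term of -11.52 (SE 1.85, adjusted p = 0.0109 by the same edgeR test), and 24PHAS_NO293 and 24PHAS_NO296 had terms of -7.36 and -5.97. The 35 tested 24PHAS loci had edgeR terms from -8.19 to -3.17, and 2 of them passed. Camera was run on log2 CPM with a prior count of 2, a scale that shrinks loci with few UMIs and on which the median term of the list was -1.42; camera with the preset correlation gave it an adjusted p of 1.69e-11 and with an estimated correlation an adjusted p of 0.638. DESeq2's Wald test called 0.382% of the tested genes against 0.846% by edgeR, and leaving out single lengths gave 0.301% (without 3.0 mm) to 1.95% (without 0.5 mm). Without pool 7 of set 8.18.21 edgeR called 2.51%, and with set as a covariate 3.30%. Of 60 orders of the lengths, the real one included, 4 gave as many genes, so chance was not excluded by number. The call of zma-MIR2275c did not hold by DESeq2 or with equal weight per cell, and it was not among the tested genes without 1.25 mm, without 1.5 mm or without clusters 6 and 8.

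The third comparison asked which genes changed with length inside a group of like cells. Clustering gave 17 clusters, compared by number because the marker lists named none; 7 had sums of at least 5 cells at 6 or more lengths. In cluster 2 (1.5 to 3.0 mm) 28 genes rose and 29 fell. PSAH rose from 586.2 ± 153.5 to 1197 ± 164.45 CPM between the 3 shortest and 3 longest lengths of that cluster, RBCS from 2030 ± 234.4 to 3702 ± 500.5 CPM, the plastid envelope gene cemA from 8296 ± 819 to 14754 ± 4190 CPM, psbH from 1267 ± 333.8 to 1906 ± 287.4 CPM and psbC from 8837 ± 696 to 13106 ± 2327 CPM. In the same cells the alpha-tubulin genes TUBA1 and TUBA3 fell (slopes -1.93, SE 0.36, and -1.63, SE 0.38), as did HMGIY2 (-1.86, SE 0.37), ATPA (-1.18, SE 0.29) and SAMDC, the S-adenosylmethionine decarboxylase of polyamine synthesis (-0.88, SE 0.27).

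In cluster 1 (0.5 to 2.5 mm) 46 genes rose and 53 fell. MNB1B fell from 4015 ± 784 to 1708 ± 524 CPM there, and ATPA rose with a slope of 0.95 (SE 0.30), the opposite sign to its slope in cluster 2, a difference that was not tested. In cluster 4 (0.5 to 2.0 mm) 8 genes rose and 1, HMGIY2, fell, from 2359 ± 1124 to 279.6 ± 67.2 CPM (slope -2.34, SE 0.52). In cluster 5 15 genes rose and 3 fell. In cluster 3 3 rose and 2 fell, and in cluster 7 2 fell and 0 rose. In cluster 11 edgeR called 0 of 76 genes, with 12 at an unadjusted p under 0.05. Altogether 170 of the 840 genes tested in at least 1 cluster changed in 1 or more clusters by edgeR's quasi-likelihood test. Each of these named genes lost its call within a cluster when at least 1 length was left out (43 refits, against 48 that kept the call), PSAH without 1.5, 1.75, 2.0, 2.75 or 3.0 mm, RBCS without 1.75, 2.75 or 3.0 mm and TUBA1 without 1.5 mm, with no change of sign. Among gene lists within clusters, nuclear photosynthesis rose in cluster 2 (4 of 4 members; adjusted p 0.0476 by camera over the lists of that cluster, 0.32 over all clusters, and adjusted p = 0.166 with an estimated correlation). In cluster 3 the plastid list went down (1 of 10 members had a positive slope; adjusted p 0.0147 by camera, 0.206 over all clusters, adjusted p = 0.66 with an estimated correlation).

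The fourth comparison asked whether slopes differed between 2 clusters sampled from anthers of the same lengths. Clusters 2 and 5 were taken because, after clustering, they shared the most lengths and cells (7 lengths). By edgeR's quasi-likelihood test of the interaction 0 of 904 genes differed, with 65 at an unadjusted p under 0.05, and the 58 named genes tested were among those without a call. In simulated data at this size the test found 35.8% of differences of 2 log2 units per mm and 87.9% of differences of 4, so smaller differences would mostly be missed.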

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

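The tests of chance for the straight and the curved courses, of photosynthetic cell share and of the resemblance of clusters 6 and 8 to their pools were chosen before their results were seen; every other test in the closing section was chosen after. Pools of 1 length were compared for 21PHAS, 24PHAS, C2, pollen, photosynthesis and chromatin genes, and 15 of 47 groups held a pool far from the rest of its length. The rule takes about 5% of groups as the share by chance. Where all other pools of a length have 0 UMIs, however, any UMI in 1 pool sets it apart. The 5% is therefore no baseline for genes with few UMIs. The pollen genes were taken from the symbols of the table after their levels had been seen.

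Clusters 6 and 8 and pool 7 of set 8.18.21 stood apart first: cells of cluster 6 fell into the same well number of different pools 2.87 times as often as the mean of 1000 permutations of clusters within pools, and those of cluster 8 4.01 times, against 1.31 and 1.50 times in the highest permutations (permutation p = 0.000999, the smallest they can give), which argues against distinct cell types alone, since sorted cells should reach any well. A mix of the pool's RNA read through some barcodes could give such wells, but 3 other clusters resembled the rest of their pools more than both (medians 0.486, 0.461 and 0.459, against 0.447 for cluster 8 and 0.39 for cluster 6), which met the bound set beforehand but by less than the spread between clusters, a margin added after the values were seen, so this stays open, as do several cells in 1 well and an effect of the barcodes. The 14 cells of pool 7, labelled 0.5 mm, were all in cluster 6 and held 24PHAS at 7081 CPM, C2 at 1323 CPM and nuclear photosynthesis genes at 1712 CPM, each far above the other 0.5 mm pools (for 24PHAS the highest of their upper bounds was 430.1 CPM). Within its set the pool correlated best with 1.75 mm (r = 0.54 across genes, against 0.005 with 0.5 mm). In 100% of bootstraps over genes the best length was from 1.25 to 1.75 mm, the outcome set for RNA of longer anthers of the same set. Cluster 6 otherwise held mainly cells of 1.25 mm (51), 1.5 mm (28) and 1.75 mm (18), and 88 of its cells, pool 7 included, were of this set. Its cells of other lengths stayed in the sums the pool was compared with. The match therefore cannot tell longer anthers from whatever else the cells of cluster 6 share. Against other sets 0.75 mm (r = 0.23) and 1.25 mm (r = 0.225) were about level. Pool 2 of the set at 1.75 mm itself correlated best with 0.75 mm of the other sets (r = 0.26, against -0.197 with 1.75 mm). Chromatin and DNA replication genes together were at 3828 CPM in the pool, against 7855 CPM in pool 8 and 3337 CPM at 1.75 mm of the set, but HMGIY2, ROA2 and DMT105 (1198, 248.99 and 295.7 CPM) were above 1.75 mm of the set (972.7, 167.5 and 199.7 CPM, within overlapping 95% Poisson intervals), and ROA2 and DMT105 near the other 0.5 mm cells (261.7 and 327.2 CPM), so a part of 0.5 mm RNA in the pool stays open.

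Pollen genes in pool 2 of set 3.29.22 at 3.0 mm were the next pattern: EXPB1, EXPB10, EXPB11, PRO3, PG6, ADF2 and MGS1 together reached 23235 CPM (826 UMIs), with 0 UMIs in the other 3.0 mm cells and 3.34 CPM over all cells outside the pool. The highest upper bound among the other 3.0 mm pools with at least 8 cells was 156.2 CPM. When the cells of the pool were split by the EXPB genes alone, PRO3, PG6, ADF2 and MGS1 stood at 16912 CPM in the 13 cells with an EXPB UMI and at 271.4 CPM (73.95 to 695) in the 14 cells with none, which argues against free RNA spread evenly over the cells of the pool. Of 12 high cells 10 had well numbers in the 2 commonest remainders on division by 16, against 5.46 by chance (permutation p = 4e-05). The divisor and the use of 2 remainders were chosen after the data were seen. The permutation redrew the wells only, so its p does not allow for that choice. A source tied to places on the plate, such as pollen or pollen RNA in some wells, may have added them but stays open. Pollen-bearing anthers under this label were not tested.

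24PHAS at 2.0 mm in set MiSeq was the remaining pattern, at 14444 CPM (1112 UMIs), and pool 2 of that set alone at 20998 CPM. Over all sets 16 cells of 2.0 mm had a 24PHAS UMI, and the 7 cells with the most held 98.9% of these UMIs. The level of the set therefore rests on few cells, while the correlations that follow are of its whole sum. The highest upper bound in the other 2.0 mm sets was 37.5 CPM. Over the other genes the set correlated best with the 2.0 mm cells of the other sets (r = 0.439), most of whose UMIs were from set Pilot, but without set Pilot it correlated best with 1.5 mm (r = 0.239, against -0.164 for 2.0 mm). Whether the whole set came from shorter anthers or was like set Pilot for another reason therefore cannot be told apart, and the 2.0 mm cells of set 7.21 also correlated weakly with the 2.0 mm cells of the other sets (r = 0.0831). Plants that differ in timing were not tested.

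The other values far from the rest of their length were these. At 0.5 mm 21PHAS stood at 1512 CPM in pool 8 of set 8.18.21, against 48.4 CPM in the next pool. At 0.75 mm chromatin and DNA replication genes stood at 11588 CPM in pool 5 of set 7.21, against 5726 CPM. At 1.0 mm C2 stood at 538 CPM in pool 2 of set 8.18.21, against 83.6 CPM. At 1.25 mm 21PHAS was at 0 CPM in pool 1 of set 1.4.21, against 19.8 CPM in the next pool, but 0 UMIs allow up to 166.05 CPM there, so the pool cannot be set apart. Pollen genes were at 97.999 CPM (5 UMIs) in pool 2 of set 8.18.21 at 1.5 mm, at 40.1 CPM (1 UMI) in pool 1 of set 3.29.22 at 2.25 mm and at 16.1 CPM (4 UMIs) in pool 1 of set 8.18.21 at 2.5 mm. At 2.0 mm 21PHAS stood at 556 CPM in pool 1 of set MiSeq, against 199.98 CPM. At 2.25 mm 21PHAS stood at 120.3 CPM (3 UMIs) in pool 1 of set 3.29.22, against 0, and nuclear photosynthesis genes at 4898 CPM in pool 4 of set 8.18.21, against 2646 CPM.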

How the results depend on the processing

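Settings that leave out pools, set MiSeq, clusters 6 and 8, or sets Pilot and MiSeq for curved courses, library size scaling, the alternatives for list courses and the splits for clusters 2 and 5 were chosen after the data were seen. Values for genes are percent of tested genes past the test, while moves by over 1.5 times were judged on numbers of genes. The straight trend was at 30.2% (1670 genes) and moved to 11.9% with no filter on low counts (2635 genes, of more tested), 39.8% with at least 2000 UMIs per cell (948 genes, of fewer tested), 28.2% within set 1.4.21 (fewer tested), 17.7% within set 8.18.21 (719 genes) and 4.05% with set and number as a replicate block (83.7% of these calls rose, against 53.0% of the 1670, and 83.1% of them were among the 1670). Pools of the same set and number deviated together in part (17 of 40 pairs with r over 0.1, median 0.086). The median r was lower for pools of the same set with another number (0.035) and for pools of other sets (-0.015). The number therefore grouped pools to some degree, although what it stands for is not given. The lower share under the block cannot be set aside on this ground. With equal weight per cell 1660 genes passed, 432 up and 1228 down. The other settings stayed within 1.5 times; leaving out each length gave 21.7% (without 0.5 mm) to 29.0%. Of 60 splits that reassign lengths, the real order was the 1 with as many genes (highest other 77). This is the smallest share that 60 splits can give, and it argues against a chance order of the lengths. Reassigning lengths cannot tell length apart from sets or pools, since these cover the lengths unevenly.

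Curved courses, at 0.846% (62 genes), were at 0.382% by DESeq2, 1.50% with no filter (more genes, of more tested), 0.945% with at least 2000 UMIs (34 genes, of fewer tested), 0.0955% with equal weight per cell, 3.30% with set as a covariate, 0.557% without sets Pilot and MiSeq, 2.51% without pool 7 of set 8.18.21 and 2.32% without clusters 6 and 8, where zma-MIR2275c was not among the tested genes. Leaving out each length gave 0.301% to 1.95%. By number chance cannot be excluded, since 4 of 60 splits gave as many (highest other 944). In all 3 such other draws the squared term correlated with real length (-0.775, 0.69 and 0.885), so they carried the straight trend, a structure of the samples, and were not draws without change.

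List trends went from 4 to 1 with an estimated correlation, and list courses from 1 to 0 with an estimated correlation and to 2 without clusters 6 and 8. Camera's direction for the nuclear photosynthesis course turned from up to down without pool 7 (median term -0.24) and without clusters 6 and 8 (-0.35). It was not past the test in either, and the median term was already -0.0046 in the main fit. Changes within clusters went from 20.2% (170 genes) to 2.95% with no filter, which was 639 genes of more tested. The difference between clusters 2 and 5 was at 0 by edgeR (65 genes at an unadjusted p under 0.05), or at 1 without 2.75 mm; any of the 64 splits gives at least 0 (the highest other 42.9% of tested genes), so the splits say nothing about chance here. Where no construction is named the cause was not tested. Low UMIs per cell limit statements on single cells and on genes under the filter.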

Other observations

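All tests in this part but that of photosynthetic cell share were chosen after the result was seen. SCR and TD1 are named here after their values were seen. SCR, a SCARECROW transcription factor gene that acts in ground tissue patterning, fell from 172.2 ± 70.9 CPM at the 3 shortest lengths to 17.9 ± 4.06 CPM at the 3 longest (slope -1.42 log2 units per mm, SE 0.20). TD1, a receptor-like kinase gene that limits meristem size, fell from 177.3 ± 80.7 to 19.4 ± 21.9 CPM (slope -1.42, SE 0.30). The miR159 precursors were highest at 1.5 mm with 180.7 CPM (122.7 to 256.4, 95% Poisson interval) and 1.75 mm with 283.6 CPM (218.4 to 362.2). At 1.5 mm they had UMIs in all 3 sets, but at 1.75 mm they stood at 412.3 CPM in set 8.18.21 and had 0 UMIs in set 1.4.21, which allows up to 42.6 CPM. They were at 33.7 CPM at 0.5 mm, all from pool 7 of set 8.18.21, whose cells were in recurring wells, and at 27.4 CPM at 2.0 mm, where set MiSeq stood at 506.6 CPM, with 0 UMIs at 0.75, 1.0 and 1.25 mm, where a count of 0 allows up to 14.6, 12.3 and 14.0 CPM, and at 2.25 mm and longer.

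As a hypothesis found in these data, zma-MIR2275c and 24PHAS transcripts may sit in the same cells. The test was narrowed to cells outside the clusters with recurring wells (of the clustering without PHAS and microRNA rows) after its result in all cells had been seen, and cells were reassigned within pools, since both transcripts differed between sets. The 9 cells of 1.25 to 1.75 mm with a zma-MIR2275c UMI had a median of 5.23% of their UMIs from 24PHAS loci, against 0% in the cells without one (permutation within pools, two-sided p = 0.00011; 6 pools held both kinds of cell). Deeper cells show both more readily: the median was 1535 UMIs in the 9 cells and 969 in the others.

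The summed level of the nuclear photosynthesis genes rose by 1.45 log2 units per mm (SE 0.13) in all cells and by 0.79 (SE 0.11) without cluster 2, 54.7% of the slope. Since 5 of the 9 genes of this list were among the leading genes of cluster 2, leaving it out lowers the slope whether the share of such cells grew or their levels rose, so the value decides nothing between these.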
